A study of Mus musculus with 8 samples.

How the data were processed

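NOMe-seq was measured in 8 libraries from mouse embryonic fibroblasts (MEFs), of which 4 came from control cells (day 0) and 4 from cells on day 1 of Etv2-induced reprogramming. In NOMe-seq, nuclei are treated with M.CviPI, an enzyme that methylates cytosines in GpC where DNA is not covered by nucleosomes or other proteins, and bisulfite sequencing then reads that methylation. On each day 2 libraries had received the enzyme (treated) and 2 had not (untreated), which gives 4 groups of 2 libraries.

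The deposited files hold 1 line per cytosine and library, on genome build mm10 per the labels. The authors gave each cytosine the fraction of its reads that were methylated, rounded to 2 decimals, and the count of reads over it in a deposited column of its own. Neither column has a header, and both units were read from the values: each fraction times its count was a whole number within rounding at every site (100%), and the fewest reads at any site were 3. The aligner, the caller, the sequence context and the handling of duplicates are not given in the sources used here. The levels were low without the enzyme and far higher with it, so the calls were read as GpC cytosines. No base context and no separate CpG calls are in the columns, and the comparison planned on CpG methylation was therefore made on all calls of the untreated libraries. Methylated reads per site were taken as the rounded product of fraction and count.

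Gene coordinates came from a RefSeq annotation of the same build without strand, so that 34610 genes on the autosomes, X and Y (21883 protein-coding and 12727 lncRNA) entered with both of their annotated ends. A gene end is thus either a transcription start or a transcript end, and a window of 1000 bp on each side of both ends stands in for the promoter. The annotation has no exons, so sites were classed as gene end, gene body or intergenic. Motif sites of ETS factors and CpG-dense windows need the genome sequence and were not analysed here.

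The tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined, except where an addition is named. For each gene end pair, calls were summed and log2((methylated + 1)/(unmethylated + 1)) was fitted in limma 3.58.1 (R 4.3.3) with a mean per group over all 8 libraries and eBayes trended on log2 mean coverage. Genes needed 20 calls in every library for accessibility and 10 for the untreated level, and the Benjamini-Hochberg threshold was 0.05. Because only 43 genes had 20 calls at their ends in every library, whole gene loci (the gene and 1000 bp on each side) were added after coverage was seen, with edgeR 4.0.16 quasi-likelihood on methylated and unmethylated counts. The fits were tested on simulated data with the real coverage, independent reads and an assumed SD between libraries of 0.3 in natural log odds. Only accessibility between the treated libraries was simulated, so false calls of the net and untreated fits were not measured. At gene loci edgeR found 47% of 100 simulated changes of 2 on the log2 odds scale and 1% of those of 1, with 2 false calls; at gene ends limma found 1 of 4 and 0 of 6.

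Levels per library are pooled methylated calls over all calls, and group means were compared with exact two-sided permutation tests, for which 2 against 2 libraries cannot go below p = 0.33. The difference between the day effects with and without the enzyme was tested by exact permutation of the days within treated and untreated libraries, with a smallest p of 0.0556. Around gene ends the centre ran from -150 to 50 bp (negative is outside the gene) and the flanks from 500 to 1000 bp on each side. Intervals of 95% come from 2000 bootstrap resamples of genes or gene ends, of 1 Mb blocks, or 1000 resamples of 1000 bp blocks, and hold the libraries fixed. Intervals of single genes are exact Clopper-Pearson intervals and cover counting error only. A comparison restricted to gene ends or blocks with calls on both days was added after the unrestricted values were seen, with each end weighted by its calls.

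There were 15 gene lists, written from general knowledge: endothelial, endothelial and blood transcription factors, blood, fibroblast and matrix, mesenchymal transcription factors, pluripotency, neural, muscle and heart, liver and gut, housekeeping, chromatin remodelling and DNA methylation, cell cycle, Hox, imprinted, and germline. They were tested with limma's camera at a preset correlation of 0.01 on the gene-locus values, where a list needed 3 tested members. Too few members were covered at gene ends for camera, so pooled levels of each list within 1000 bp of gene ends were added, with sites over 100 reads left out and 10000 random lists matched on deciles of coverage for comparison. The correlation between neighbouring sites by distance, the share of sites per chromosome and a chi-square between libraries at gene loci with 20 calls were added as well. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for these.

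The rule for named genes was fixed in advance. In the fits of accessibility and of the untreated level, up to 10 genes per direction are named that pass the threshold with no overlap between the libraries of the days, by size of change, and where fewer than 5 pass, the 5 with the smallest p. The rule did not cover the net fits, so their genes were named after their values were seen. A set of 16 endothelial, blood, fibroblast and housekeeping genes is given whatever its values. Alternatives covered the call minimum, the window, the added count, centring, the plain fraction, the libraries in the fit, a replicate block, the tool, highly covered sites, and leaving out each library in turn.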

Results

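GpC methylation was read in 8 bisulfite libraries of mouse embryonic fibroblasts, 2 libraries in each of 4 groups: day 0 and day 1 of Etv2-induced reprogramming, each without (untreated) and with (treated) the GpC methyltransferase M.CviPI. Etv2 is a transcription factor of the ETS family that drives endothelial and blood fates. The day 0 untreated libraries covered 502588 and 439527 sites with 1898356 and 1693307 calls, where a call is 1 read over 1 site. The day 0 treated libraries covered 568331 and 559372 sites (2138058 and 2123335 calls). On day 1 the untreated libraries covered 1012656 and 991688 sites (3577740 and 3507942 calls) and the treated ones 792322 and 810078 sites (2856034 and 2917131 calls). The median site had 3 reads in every library, and from 87.2% to 88.1% of sites had exactly 3, and values were therefore pooled over genes or classes. Only 10131 sites were covered in all 8 libraries. The labels do not say whether the 2 libraries of a group came from separate cultures, so they may be technical replicates. The p-values of the fits by gene measure the spread between these samples, and exact permutation p-values reassign the same samples. Those of camera and of random lists compare genes, and Fisher's exact p counts reads.

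Chromosomes contributed different shares of the sites on the 2 days. Chromosome 3 held 6.82% ± 0.163 (SD, n = 4) of the autosomal sites on day 0 and 3.65% ± 0.0337 on day 1, a log2 ratio of -0.90. Chromosomes 12 and 13 also lost share, with log2 ratios of -0.60 and -0.50, and chromosomes 1, 16, 17 and 19 gained, with log2 ratios of 0.32, 0.31, 0.31 and 0.34. For 19 of the 20 chromosomes tested (the autosomes and X), the 4 libraries of day 0 did not overlap the 4 of day 1 (exact permutation p = 0.0286 each, the smallest possible, n = 4; adjusted p = 0.0301); chromosome 18 was the exception. A chance split separates 4 against 4 libraries with that same probability. The 4 libraries of a day are 2 treated and 2 untreated ones, which may come from the same cells. Shares of the autosomal sites also depend on each other, so the 19 results are not independent.

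**Figure D1:**
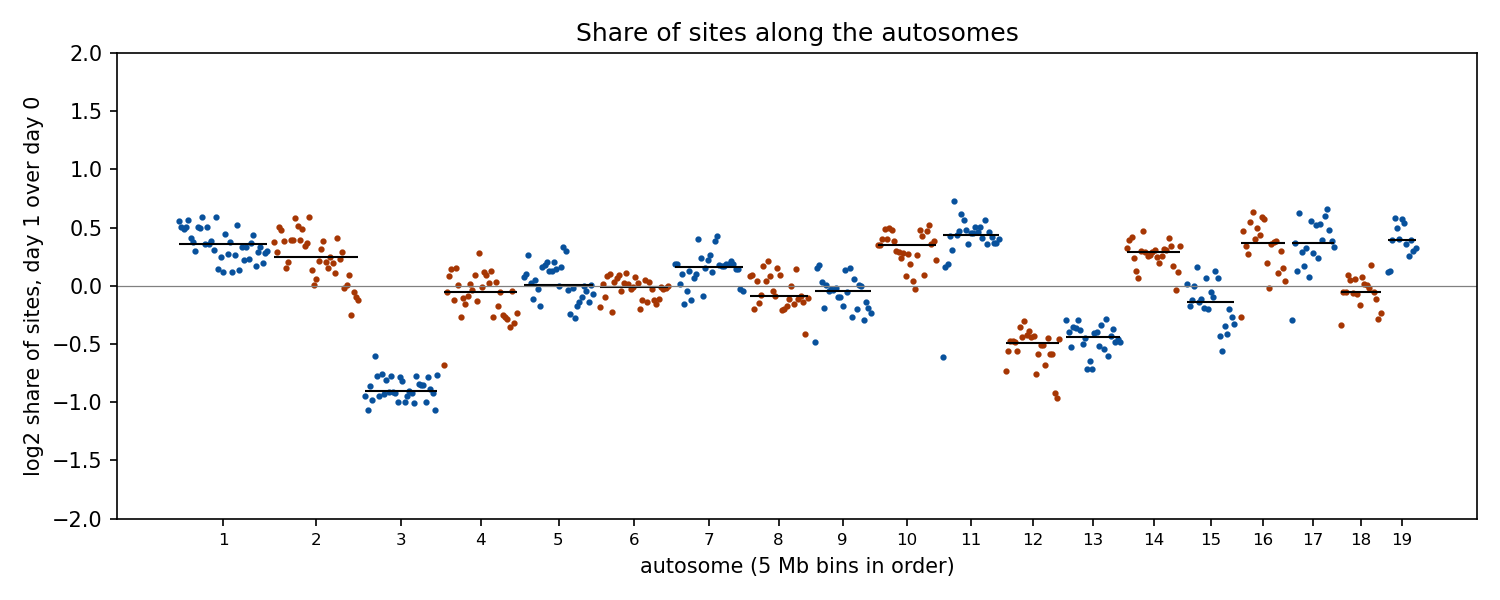
Log2 ratio of the share of sites, day 1 over day 0, in 5 Mb bins along the 19 autosomes; each point is a bin and black lines are chromosome medians. The 32 bins of chromosome 3 lie between -1.07 and -0.60.

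The comparison with and without M.CviPI measures how far the readout stands above background. Treatment raised the pooled GpC level from 4.81% ± 0.242 (SD, n = 2) to 31.2% ± 0.169 on day 0, and from 2.93% ± 0.0315 to 32.0% ± 0.00432 on day 1. The differences of 26.4 and 29.0 percentage points are far larger than the spread between replicates, and no treated library overlapped an untreated one (exact permutation p = 0.33, the smallest possible with n = 2). Gene ends reached 35.5% and 34.5% with the enzyme against 1.73% and 1.14% without it. The background was 15.4% of the treated level on day 0 and 9.18% on day 1. Much of it sat at a few sites with very many reads: with sites over 100 reads left out, the autosomes had 2.34% and 1.10% without the enzyme.

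**Figure D2:**
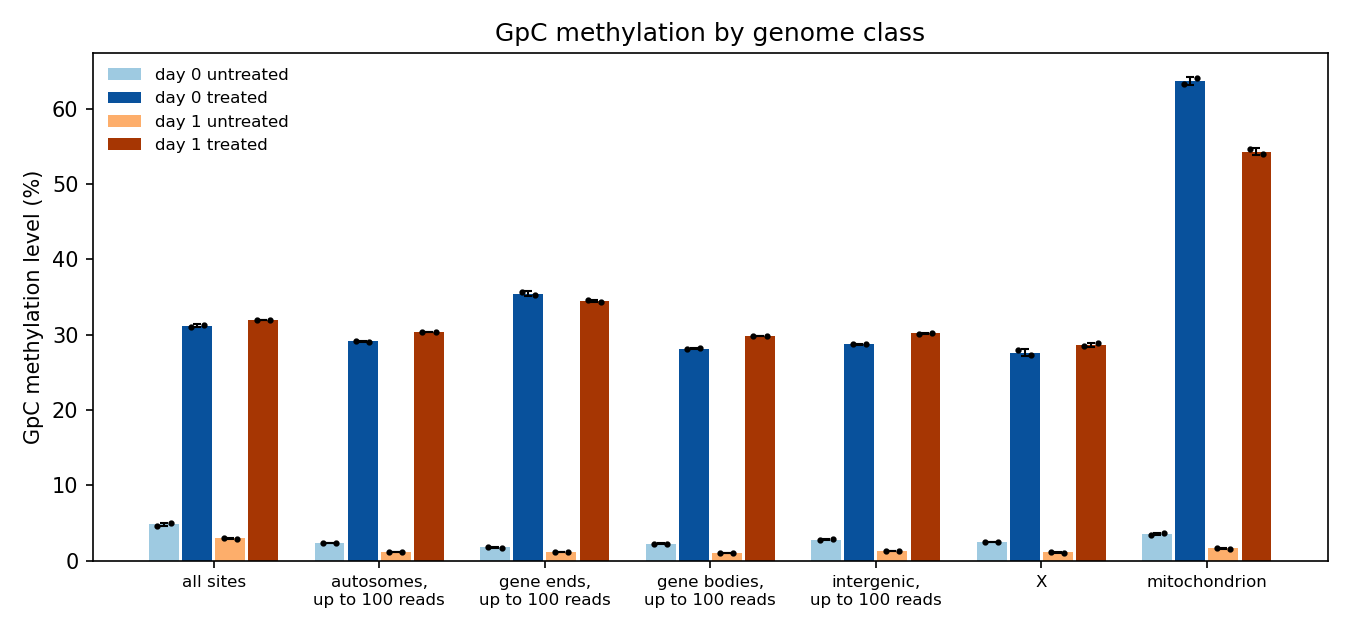
GpC methylation level (%) by genome class; bars are group means, error bars SD, and points the 2 libraries of each group. Treated mitochondrial DNA fell from 63.7% to 54.3% while treated gene ends fell by 0.973 percentage points and treated gene bodies rose by 1.66.

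The genome-wide comparison of the days asks whether accessibility as a whole shifted during the first day of reprogramming. The treated level was 0.770 percentage points higher on day 1 over all sites, and 1.27 points higher on the autosomes with sites over 100 reads left out (95% bootstrap interval 1.01 to 1.48). All 19 autosomes moved this way, by 0.345 to 2.15 points. Gene bodies rose from 28.3% to 30.0% and intergenic DNA from 32.9% to 33.4%, and the X chromosome rose from 27.6% to 28.7%. Over the 89733 blocks of 1000 bp with treated calls on both days, the rise was 1.98 points (interval 1.75 to 2.24). The untreated level fell by 1.87 points over all sites and on all 19 autosomes, but rose by 0.290 points at sites with at least 5 calls. At the 10131 sites covered in all 8 libraries, a small part of the sites of any library, it rose by 1.49 points. Mitochondrial DNA went the other way from the nuclear genome with the enzyme, from 63.7% ± 0.527 (SD, n = 2) to 54.3% ± 0.465. Each of these changes exceeded the spread between replicates, and each exact permutation p of treated or untreated libraries was 0.33 (n = 2), the smallest possible. The net change, treated minus untreated, was 2.64 points over all sites (exact permutation p = 0.0556, the smallest possible, n = 2).

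The profile around gene ends tests whether the enzyme reports the open DNA known at promoters. Treated levels peaked at the ends of protein-coding genes. The centre had 54.0% ± 0.272 (SD, n = 2) on day 0 against 33.0% in the flanks, an excess of 21.01 points, and 47.6% ± 0.288 on day 1 against 33.0%, an excess of 14.7 points. In untreated libraries the centre lay below the flanks on day 0, by a difference of -0.346 points ± 0.12, and slightly above them on day 1, by 0.586 points ± 0.228 (SD, n = 2). Over all covered gene ends the treated centre fell by 6.41 points, but the ends covered differed between the days. Over the 432 ends with treated calls on both days, the centre changed by 0.581 points (95% bootstrap interval -2.55 to 3.55). Gene ends with treated calls on day 0 alone had 54.3% at the centre (2372 ends) and those with calls on day 1 alone 46.8% (2734 ends). Within 1000 bp the same comparison over 9374 ends gave -0.225 points (interval -0.866 to 0.386), and in the flanks 1.63 points (interval 0.652 to 2.65). Over the same ends the lower centre of day 1 was not seen. At ends covered in both replicates of a day, the treated centre differed between them by -3.04 points on day 0 and -1.62 on day 1. The flanks rose by more than the centre, over another set of ends, so an unchanged excess of the centre was not shown. The exact permutation p of the centre change over all ends was 0.33 (n = 2), the smallest possible.

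**Figure D3:**
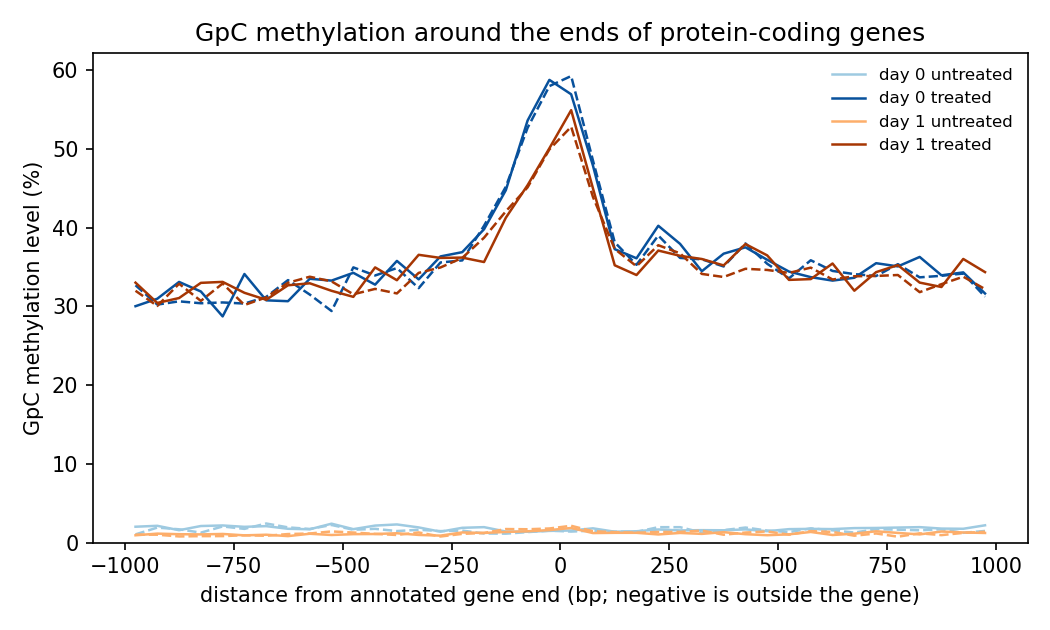
GpC methylation level (%) in 50 bp steps from the annotated ends of protein-coding genes, where negative distances are outside the gene; each line is a library, solid and dashed for the 2 replicates. The highest step means of the treated libraries are 58.4% on day 0 (-50 to -1 bp) and 53.9% on day 1 (0 to 49 bp), over gene ends that differ between the days.

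Levels at neighbouring sites carry the spacing of nucleosomes. In treated libraries the correlation between sites on the autosomes was negative at distances above 70 and up to 100 bp, at -0.0523 ± 0.00437 (SD, n = 2) on day 0 and -0.133 ± 0.00629 on day 1. It was positive again above 160 and up to 190 bp, at 0.0984 and 0.106. The swing between these distances grew from 0.151 to 0.239 (exact permutation p = 0.33, the smallest possible, n = 2). Untreated libraries had no dip below 0 at the shorter distance, with 0.103 there on both days. Their correlation also varied with distance. It was 0.0335 on day 0 and 0.0580 on day 1 above 160 and up to 190 bp. At 231 to 240 bp it was higher, at 0.0557 to 0.113 by library. These correlations are across sites, which are not independent replicates.

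**Figure D4:**
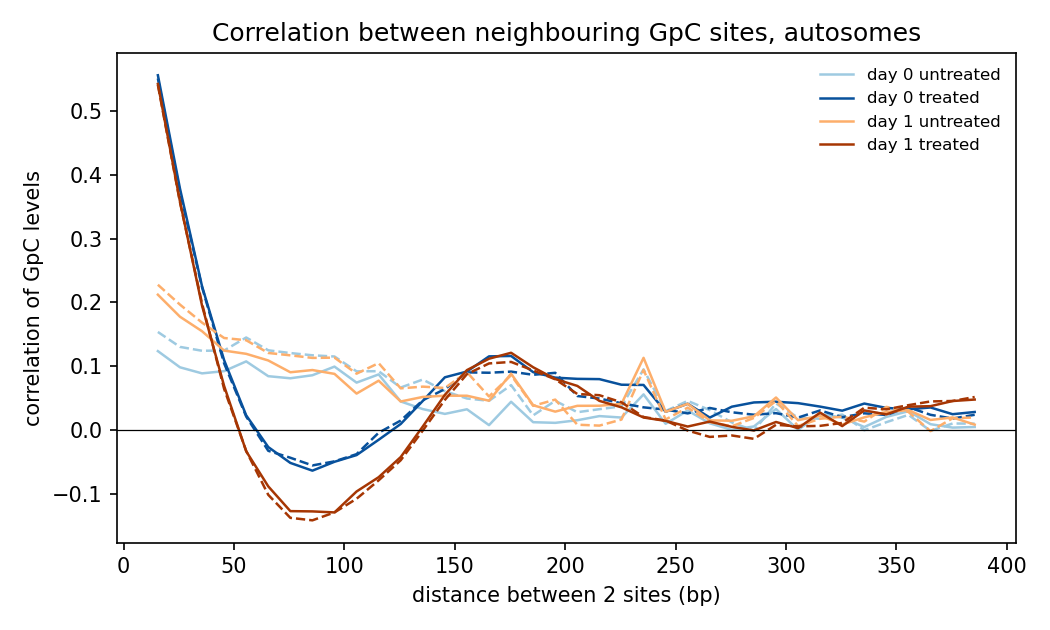
Correlation of GpC levels between 2 autosomal sites by their distance (bp, in 10 bp steps from 11 bp); each line is a library. Treated libraries dip below 0 between 70 and 100 bp and more so on day 1 (-0.133) than on day 0 (-0.0523).

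Accessibility of single promoters, day 1 against day 0, asks which genes open or close as Etv2 acts. At gene ends, limma on 8 libraries called 0 of 43 genes (3 with an unadjusted p under 0.05; edgeR 0, with 2). The smallest p among genes that rose were those of AY036118 (chromosome 17, 39848112 to 39898385, mm10), Gm39123, Znrd2, Glo1 and Ugt1a1. AY036118 went from 60.6% ± 0.155 (SD, n = 2) to 68.2% ± 0.368 with a limma adjusted p of 0.580. Among genes that fell they were Plin4, Gm40904, Lrrc24, Mroh2a and Hjurp. Plin4 (chromosome 17, 56100587 to 56109948) went from 47.8% ± 3.10 to 18.7% ± 9.43 with a limma adjusted p of 0.580. Lrrc24 rested on 1 library: its log2 odds change was -1.07, and 0.84 without replicate 1 of the day 1 treated libraries. AY036118 was also called, with Lars2 and Gm33862, when the 4 treated libraries were fitted alone. These last 2 names were chosen after their values were seen. Among simulated gene ends without a change, fits of 4 libraries made 2 false calls and fits of 8 libraries 0. AY036118, Lars2 and Gm33862 had means of 31.6, 12.1 and 11.8 reads per site, where the median site of every library had 3. Why reads were so many there was not tested. Only 43 of 34610 genes had enough calls, so most promoters were not measured.

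Over whole gene loci, 5654 genes could be tested, and edgeR called 0 (176 with an unadjusted p under 0.05; limma 0, with 70). The median change was 0.10 on the log2 odds scale. The smallest p among loci that rose belonged to Tmem217, Trank1, Fer1l5, Faf2 and Cpvl, and among loci that fell to Gna13, Itgav, Sympk, Tdp1 and Safb2. Trank1 went from 14.2% ± 8.25 (SD, n = 2) to 51.3% ± 0.511 and Gna13 from 71.7% ± 1.84 to 24.2% ± 14.0. All 10 had an edgeR adjusted p of 0.999. Treated libraries of different days differed at loci about as much as replicates did. The mean chi-square with 1 degree of freedom was 2.71 to 2.82 between days, against 2.80 between the replicates of day 0 and 2.49 between those of day 1. Untreated libraries differed more between days (2.22 to 2.33) than between replicates (1.44 on day 0 and 1.5004 on day 1). In simulations at this depth changes of 1 on the log2 odds scale were found in 1% of cases, so changes of that size were not detectable.

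Net of the untreated libraries, A530040E14Rik was the single gene called at its ends (limma log2 odds change 3.19, adjusted p = 0.0294; edgeR 0 genes), and it was chosen after its values were seen. Its untreated level fell from 3.55% ± 1.56 (SD, n = 2, on 43 and 41 calls) to 0.240% ± 0.340 (on 106 and 208 calls). Its log2 odds change was -2.64 between the untreated libraries (limma adjusted p = 0.0732). Between the treated libraries it was 0.55 (limma adjusted p = 0.909), so a gain in accessibility was not shown. Among the 43 genes tested at their ends, the number called was 6 and 1 without replicates 1 and 2 of the day 0 untreated libraries, 7 and 4 without those of the day 1 untreated libraries, and 0 without any 1 of the treated libraries. At gene loci edgeR called 202 genes, all upward, and limma 1 (Sfi1). The median net change of the 5654 loci was 1.10 on the log2 odds scale. Over the same loci the median was 0.10 between the treated libraries and -1.01 between the untreated ones (-0.97 over the 7992 loci of that fit). With each library centred on its median value, the median net change in edgeR was 0.10 and edgeR called 5 loci, all downward (Gm33838, 2700054A10Rik, Smo, and the overlapping Filip1l and Cmss1). Centred limma called 1, Gm33838, also downward. Sfi1 and the loci called after centring were chosen after their values were seen. Filip1l and Cmss1 had means of 12.6 and 11.7 reads per site over their loci, and Sfi1 13.3 at its ends. The edgeR count fell to 75 and 102 without replicates 1 and 2 of the day 0 treated libraries and to 25 and 14 without those of the day 1 treated libraries.

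The untreated libraries measure endogenous GpC methylation and unconverted cytosines, and they take the place of the CpG comparison. At gene ends limma called 0 of 144 genes (15 with an unadjusted p under 0.05; edgeR 0, with 10). The smallest p belonged to 2700054A10Rik, B130046B21Rik, Junb, Egr4 and Desi1 among genes that rose and to A530040E14Rik, Gm41331, 4931408C20Rik, Sfi1 and R3hdm4 among genes that fell, none past the threshold. At gene loci edgeR called 258 of 7992 genes, 2 up and 256 down, around a median of -0.97 on the log2 odds scale. Actr3b rose from 0.592% ± 0.158 (SD, n = 2) to 5.12% ± 5.19 (edgeR adjusted p = 0.0327), and Filip1l, which overlaps Cmss1, from 1.21% ± 0.313 to 2.60% ± 0.951 (edgeR adjusted p = 0.0477). Both calls ended in edgeR with a replicate block (adjusted p = 0.0761 for Actr3b and 0.0732 for Filip1l) and with 4 libraries (0.418 and 0.469), and in limma Filip1l had 0.0586. Without replicate 1 of the day 0 untreated libraries the edgeR adjusted p was 0.0881 for Actr3b and 0.328 for Filip1l, and without replicate 1 of the day 1 untreated libraries 0.765 and 0.502. Without replicate 2 of the day 0 untreated libraries it was 0.234 for Actr3b. Mepe, LOC115488769 and Cmss1 rose without passing. The largest fitted falls were those of Ipo9, Asah2, Gm36244, Fam107b, Irak3, Focad, Morc1, Pcdh7, Neb and Fn1, each with 0 methylated calls on day 1. A fitted change against 0 depends on the model and gives no bound. Fn1 had 3.49% ± 1.80 on day 0 (edgeR adjusted p = 0.0123) and Gm36244 4.75% ± 0.0666 (edgeR adjusted p = 0.000108). With the 4 untreated libraries fitted alone, 9 of these 10 falls did not pass in edgeR (adjusted p from 0.104 for Asah2 to 0.353 for Fam107b) and Gm36244 did (0.0373), while all 10 passed in limma (0.0168 to 0.0469). Of these 10 falls, that of Gm36244 passed without any 1 of the 4 untreated libraries. Asah2, Fam107b, Irak3, Morc1, Pcdh7 and Fn1 did not pass without replicate 1 of day 0 (adjusted p from 0.0892 to 0.241), nor Ipo9, Fam107b, Irak3, Focad, Morc1, Pcdh7 and Neb without replicate 2 of day 0 (0.0575 to 0.392). Ipo9, Asah2, Fam107b, Irak3, Morc1, Pcdh7, Neb and Fn1 did not pass without replicate 1 of day 1 (0.0702 to 0.198), nor Fam107b, Irak3, Focad, Morc1, Pcdh7 and Neb without replicate 2 of day 1 (0.0706 to 0.259). With each library centred on its median value, edgeR called 15 loci, 10 up and 5 down, among them Gm36244, Actr3b and Filip1l but none of the other 9 named falls. Limma called 1006 loci, and 8 after centring, 6 up and 2 down. At gene ends the count was 1 and 0 without replicates 1 and 2 of the day 0 untreated libraries and 6 and 1 without those of the day 1 untreated libraries. At gene loci it was 163 and 151, and 152 and 146, in the same order.

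Gene lists ask whether endothelial and blood genes opened together and fibroblast genes closed. With camera, 0 of 12 lists with at least 3 tested members were called for accessibility (lowest adjusted p = 0.834), and 0 with an estimated correlation or with fry. Adjusted over the list alone, 0 members of any of the 12 lists passed. The housekeeping, cell cycle and germline lists had too few tested members. The fibroblast and matrix list had a median below 0 (-0.019) while its test pointed up, and the liver and gut and Hox lists had medians above 0 (0.17 and 0.09) with tests pointing down. For the untreated level camera called 0 of 13 lists (lowest adjusted p = 0.777), with tests pointing up for all but the endothelial, muscle and heart and imprinted lists although every list median was below 0, and 0 held with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance and not whether they differ from other genes, called 9, all downward (lowest adjusted p = 0.00904). Adjusted over the list alone, 4 endothelial and 4 imprinted members passed there, 2 each of the endothelial and blood transcription factors, the blood, fibroblast and matrix, mesenchymal and chromatin lists, 1 of the cell cycle list and 0 of the others.

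Pooled over gene ends, the endothelial and blood transcription factors went from 25.1% ± 5.16 (SD, n = 2) to 39.0% ± 6.20, a change higher than that of 98.8% of random lists. The fibroblast and matrix genes went from 53.1% ± 11.2 to 32.2% ± 0.839, a change lower than that of all but 0.260% of random lists. The two-sided p against the random lists, adjusted over the 15 lists, was 0.183 for the transcription factors and 0.0810 for the fibroblast and matrix genes. The exact permutation p between the libraries of the days was 0.33 for both, the smallest possible. On day 0 both lists already lay far from the random lists: the fibroblast and matrix genes were at percentile 99.6 (random median 36.8%) and the transcription factors at percentile 1.17 (random median 37.0%). The two-sided p of that level against the random lists, adjusted over the 15 lists, was 0.123 and 0.177. Neither list passed. Over whole gene loci the changes were 2.48 points for the transcription factors (percentile 80.25 of random lists) and 0.491 points for the fibroblast and matrix genes (percentile 36.0). The most extreme list there was the housekeeping list, at 8.23 points (percentile 99.3, adjusted p = 0.219), from a day 0 level at percentile 0.560. Over the same gene ends on both days the changes were, for the transcription factors and the fibroblast and matrix genes, 9.10 points (95% bootstrap interval -3.89 to 22.1, 10 ends) and -12.2 points (interval -28.9 to 5.85, 13 ends). The endothelial list went from 37.9% to 31.1%, blood from 34.2% to 29.4%, mesenchymal transcription factors from 39.7% to 39.4%, pluripotency from 28.6% to 41.4%, and neural from 36.1% to 26.4%. Muscle and heart went from 38.8% to 37.8%, liver and gut from 32.5% to 31.9%, housekeeping from 35.5% to 40.7%, and chromatin remodelling and DNA methylation from 34.1% to 35.9%. Cell cycle went from 44.9% to 38.5%, Hox from 29.1% to 32.5%, imprinted from 37.9% to 29.2%, and germline from 26.8% to 29.7%. The endothelial, blood, mesenchymal, neural, muscle and heart, liver and gut, chromatin, cell cycle, Hox and germline lists also changed direction under another window or over the same gene ends. None of the 15 lists had an adjusted p under 0.05 against random lists. Over the same gene ends, 2 of 15 unadjusted intervals excluded 0: chromatin remodelling and DNA methylation (11.3 points, 1.04 to 21.3) and imprinted (-13.8 points, -25.6 to -2.68).

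**Figure D5:**
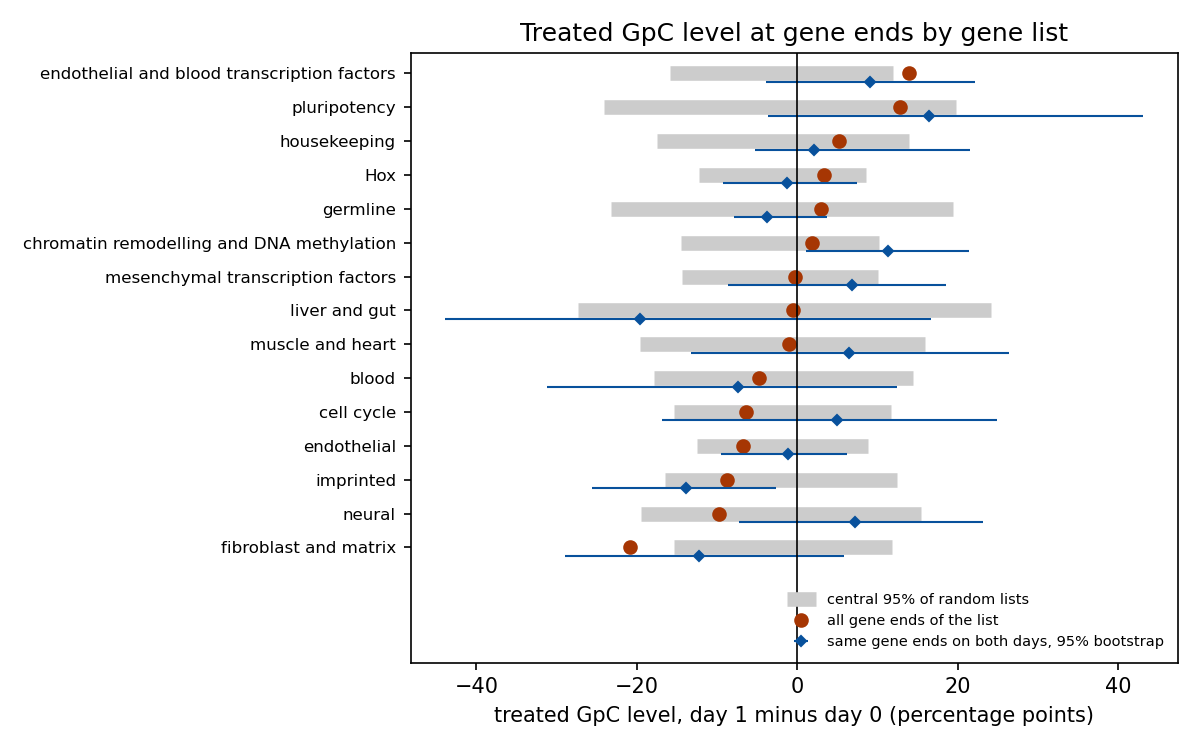
Change of the treated GpC level within 1000 bp of gene ends, day 1 minus day 0 (percentage points), for 15 gene lists; circles use all ends, diamonds the same ends on both days with 95% bootstrap intervals, and grey bars hold the central 95% of random lists. The circles of the endothelial and blood transcription factors and of the fibroblast and matrix list lie outside the grey bars, and neither passed after adjustment.

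Genes set in advance were read over their whole loci, with treated calls of both libraries pooled. Reads were not shown to be independent molecules, so the exact intervals cover counting error only. Kdr, an endothelial receptor (chromosome 5, 75932827 to 75979072), had 28.4% of 67 calls on day 0 (95% interval 18.01 to 40.7) and 18.8% of 170 on day 1 (13.2 to 25.5). Tek had 27.2% of 81 calls and 14.8% of 54, and Cdh5 27.1% of 199 and 28.6% of 224. Emcn had 6.67% of 15 and 16.7% of 48, Lmo2 33.3% of 51 and 43.7% of 87, and Tal1 26.7% of 15 and 44.4% of 9. Fli1 had 36.9% of 325 and 37.5% of 144, and Erg 24.2% of 231 and 20.5% of 302. Sox18 and Etv2 had calls on day 1 only, 21 and 18. Among fibroblast genes, Col1a1 had 26.5% of 102 calls and 34.4% of 218, Pdgfra 25.8% of 93 and 31.4% of 105, Thy1 33.3% of 3 and 30.3% of 33, and Twist1 28.6% of 21 and 3 methylated of 6. Actb had 62.5% of 24 and 62.1% of 87, and Gapdh 38.0% of 92 and 36.1% of 36. Untreated levels of these genes were at most 6.35%, except for Emcn on day 0 (27.8% of 18 calls). The lowest Fisher's exact p was that of Kdr (0.117, unadjusted, 14 genes with calls on both days). The 4 that edgeR could test (Cdh5, Fli1, Erg and Pdgfra) had an adjusted p of 0.999, and the direction of Fli1 and Pdgfra changed when 1 library was left out: -0.29 for Fli1 without replicate 2 of the day 1 treated libraries, against 0.10, and -0.04 and -0.10 for Pdgfra without replicate 2 of the day 0 and replicate 1 of the day 1 treated libraries, against 0.39.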

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

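All tests of explanations in this part were chosen after the results they address were seen, and so were their bounds. The shares per chromosome and the levels over the same gene ends were also computed only after coverage had been seen.

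The genome-wide level changed differently with and without the enzyme. The change with day in the treated libraries exceeded that in the untreated libraries by 2.64 percentage points (exact permutation p = 0.0556, the smallest possible with n = 2). The shares of sites per chromosome are not levels themselves. Levels pooled over the genome weight each chromosome by its calls, so the shares bear on them. Chromosome 3 stood out among the autosomes and X in these shares, with a log2 ratio of -0.90 between day 1 and day 0. The Y chromosome had -1.04 on few sites (0.0282% of the autosomal number on day 0 and 0.0137% on day 1), and mitochondrial DNA -0.71 (-0.97 in untreated and -0.47 in treated libraries). A region of chromosome 2 (98660001 to 98670000, mm10) stood out because its level without the enzyme was at least 30.2% in every untreated library. It held between 3.21% and 5.15% of all calls of a library on 42 to 46 sites. Its treated level was 51.2% ± 1.04 (SD, n = 2) on day 0 and 51.6% ± 0.0577 on day 1. No explanation of the chromosome 2 region was tested.

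The different shares of sites per chromosome held for all 4 libraries of each day. The lowest day 0 share of chromosome 3 was 6.64% and the highest of day 1 was 3.70%, which argues against a single misplaced library. After gene density was taken out, the mean log2 ratio of the bins of chromosome 3 was -0.90, so gene density does not account for it. Within day 1 the deeper untreated libraries differed from the treated ones in this share by -0.020 on the log2 scale, where an effect of depth would have given -0.36. The chromosome accounted for 82.2% of the variance of 496 bins of 5 Mb. A candidate explanation is that the cells of day 0 and day 1 carried whole chromosomes in different copy number, as cultured fibroblasts may. No listed site had under 3 reads, so the share of sites can change by more than the amount of DNA. If the share rose with the cube of that amount, chromosome 3 on day 1 over day 0 would stand at 0.820 of the autosome median. The cube is an assumption. The day cannot be separated from the cell population here, so whether the 2 days came from the same cells was not tested, and any difference between the days may come from the populations and not from Etv2.

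The treated level was lower on day 1 at gene end centres and in mitochondrial DNA and higher over the autosomes. Within 1000 bp of gene ends it fell by 0.973 points over all ends. Over the ends of these protein-coding genes with calls on both days the change was -0.225 points (95% bootstrap interval -0.866 to 0.386), so no fall was shown there. It was smaller than that between replicates (-0.316 on day 0 and -0.421 on day 1). At gene end sites in all 4 treated libraries it was 2.70 points. Only 12599 sites of any kind were covered in all 4, so these may not stand for gene ends in general. At gene end centres the change was 0.581 points over the 432 ends with treated calls on both days. The different gene ends covered on the 2 days may thus account for the lower centre. These 432 were a small part of the 5538 ends with treated calls at the centre, and may not stand for the rest. In mitochondrial DNA the change over the sites present in all 8 libraries was -9.62 points, which argues against different sites. A weaker enzyme reaction on day 1 in all compartments would lower the nuclear level too, but it rose by 1.98 points over the same blocks of 1000 bp. A weaker reaction in mitochondria alone and a change in mitochondrial DNA packaging remain open and were not tested.

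The untreated level was lower on day 1. More complete bisulfite conversion on day 1 would lower mitochondrial and nuclear DNA by a like ratio. The mitochondrial level on day 1 was 0.455 of that on day 0. The nuclear ratio depends on the measure: 0.469 on the autosomes with sites over 100 reads left out and 0.453 as a mean of site levels, within the bound of 20% used, but 0.610 over all sites pooled and 0.600 over the same autosomal blocks of 1000 bp, outside it. These values do not decide whether conversion differed. At gene end centres, over the 620 ends with untreated calls on both days, the level on day 1 was 1.03 of that on day 0 (1.19 over all ends covered). That is 0.677 points above what the block ratio of 0.600 would give (95% bootstrap interval over ends 0.261 to 1.14). A fall by the same ratio everywhere does not by itself account for the centres. Treated reads carried over into the untreated libraries of day 0 would raise gene end centres above their flanks, and the difference there was -0.346 points. Carry-over on day 1, where the untreated centre lay slightly above its flanks, was not tested. It would raise the centres of day 1, so the ratio at centres cannot exclude more complete conversion on that day. No biological explanation of the lower untreated level was tested.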

How the results depend on the processing

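Alternatives at gene loci, for pooled lists, for chromosome shares, over the same gene ends, blocks or sites, for lncRNA genes and for levels without sites over 100 reads were chosen after the data were seen, as were the 4-library edgeR fits. For comparisons, 167 alternative values were labelled the same, 45 moved and 5 reversed. A count of genes or lists was labelled the same within a fixed ratio of the main count, as 136 net loci were against 202. A difference of levels was labelled the same wherever its direction held, whatever its size. For pooled lists, 38 of 54 kept their direction and 16 reversed. For the named genes, 665 of 780 alternative values kept their direction and their side of the threshold, whatever their size. Of the others, 83 lost and 27 gained the threshold and 5 reversed. Where a result changed, the cause was not tested unless given.

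Accessibility at gene ends gave 0 genes, but 6 with the plain fraction, 3 with 4 libraries and 3 with edgeR on 4 libraries. Net of the untreated libraries it gave 1, but 0 with a minimum of 10 calls, 3 with 60, 2 with a window of 2000 bp, 0 with 0.5 added, 0 with centring, 4 with the plain fraction and 0 with edgeR. The untreated level at gene ends gave 0 genes, but 7 with a minimum of 30 calls (fewer genes tested), 3 with 200 bp and 3 with 2000 bp. Leaving out 1 library gave 0 to 7 genes net and 0 to 6 for the untreated level; the lone library is assumed to vary like the other groups.

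At gene loci edgeR called 0 for accessibility and 3 with 4 libraries; limma called 0, 4 on the plain fraction and 4 with 4 libraries. Net, edgeR called 202 and, with centring, 5, as the median net change moved from 1.10 to 0.10; edgeR called 14 to 191 without 1 library. Limma called 1, 1 with centring and 2 on the plain fraction. For the untreated level edgeR called 258, 15 with centring, 17 with 4 libraries and 146 to 163 without 1 library. Limma called 1006, 8 with centring, 0 on the plain fraction and 96 with 4 libraries. With a replicate block the counts at gene loci were 0, 136 and 189. Camera called 0 lists for the untreated level and fry 9.

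With 200 bp the changes in points were 0.901 for endothelial, 8.58 for mesenchymal transcription factors, -12.1 for chromatin and -1.07 for Hox. Over gene loci they were 1.30 for endothelial, 2.04 for blood, 0.491 for fibroblast and matrix, 1.67 for neural, 4.13 for muscle and heart and 2.02 for liver and gut. Over the same gene ends they were 6.84 for mesenchymal transcription factors, 7.15 for neural, 6.43 for muscle and heart, 4.9996 for cell cycle, -1.25 for Hox and -3.80 for germline.

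The untreated genome level changed by 0.290 points at sites with at least 5 calls and by 1.49 at sites in all 8 libraries. The gene end centre changed by 0.581 points over the same ends, and by 0.344 with the centre from -100 to 100 bp. Gene ends within 1000 bp changed by 2.70 points at sites in all 4 treated libraries. On the log2 odds scale Hjurp changed by 0.029 with 2000 bp. Without 1 library Fli1 ran from -0.29 to 0.61, Lrrc24 from -2.97 to 0.84 and Pdgfra from -0.10 to 1.02.

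Strict sequence context, all GpC or CpG, ETS motif settings, DESeq2 with size factors, region settings, the 200 bp window for camera and the 4-library fit of the net change were not run, for lack of context, genome sequence, count tables, covered members or libraries. A minimum of 3 calls per site removes no site. Depth limits single genes: a simulated log2 odds change of 1 at gene loci was found in 1% of cases.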

Other observations

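The tests in this part were chosen after the data were seen. At sites with exactly 3 reads in replicate 1 of the treated libraries of day 0, 3.46% were methylated on all 3 reads, against 2.35% for independent draws at 1 level, and 38.4% on none, against 36.3%. At gene loci the mean chi-square with 1 degree of freedom between replicates was 1.44 on day 0 and 1.5004 on day 1 without the enzyme, against 2.80 and 2.49 with it. Deviations of replicates with the same number in different groups correlated between -0.024 and 0.0189 over 5654 loci, so replicate numbers showed no shared deviation at gene loci.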
